A study of Mus musculus with 12 samples.

How the data were processed

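Hippocampal polyA RNA of 12 mice was sequenced, with 3 animals in each of 4 groups per the labels, so that the spread is between animals. The deposited table holds FPKM (fragments per kilobase of gene, scaled to library size) made by the authors for 54532 Ensembl genes. Alignment with HISAT2 2.0.5 and counting with featureCounts 1.5.0-p3 on mm10 are listed in the submitters' processing notes. The strand setting and the treatment of fragments shared between genes are not given in the sources used here. Members of families with near-identical copies (H2-Q, Saa, Hba, Hbb, Gbp, Ifit3) and overlapping genes are therefore uncertain. Of the identifiers, 54409 were found in GENCODE vM21, and 53499 had the same position there. Coordinates are those of the deposited table.

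FPKM times gene length gave whole multiples of a single step per library within 0.01 for 100% of the 309337 values above 0, so whole fragments were recovered. Their totals ranged from 16979666 to 24105022. The divisor of the authors' FPKM differed from these totals by -2.0% to 3.1%, and how it was set is not given in the sources used here. The value of 1 fragment in a gene of 1 kb lay between 0.0402 and 0.0587 FPKM, so levels of a few hundredths of an FPKM rest on few fragments. Pairs of replicates differed by more than sampling noise, with a chi-square per gene of 3.78 to 12.5, and none was a repeat of another. The sex of the pups is not given in the labels.

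Genes with at least 0.5 FPKM in at least 3 libraries were tested (17687 genes, 13972 of them protein coding). A linear model with 1 mean per group and 8 residual degrees of freedom was fitted to log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean trend. Tests were two-sided, with Benjamini-Hochberg adjustment within each of 8 comparisons and a threshold of 0.05. All adjusted p are from limma. An exact permutation test of 3 against 3 animals cannot go below a two-sided p of 0.1, so no gene or list was tested that way. Splits of the labels were run for the counts of calls alone. On simulated counts with 200 changed genes among 17499 tested, the SL against SS comparison recovered 56.2% of 1.5-fold, 80.0% of 2-fold and 92.3% of 4-fold changes and called 7 unchanged genes. The interaction recovered 29.7%, 66.2% and 87.7% of the same fold sizes and called 4 unchanged genes. The simulated dispersion was 0.00361, a median over genes, so these shares do not stand for genes with a larger spread.

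The 42 gene lists were fixed before the data were examined, and 38 with at least 5 tested members were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed at the same time. It took up to 8 protein-coding genes with the largest changes in each direction among those called, with a group mean of at least 1 FPKM. In comparisons of 2 groups, but not in the interaction or the averages, these also had no overlap between the groups. Without these limits, it added up to 3 called genes per list and 12 genes named in every comparison. Other settings were quantile normalization, median centring, pseudocounts of 0.1 and 1, no filter, a filter of 2 FPKM, the replicate number as a block, only the groups compared, robust moderation, library weights, limma voom on the whole fragments, a Y-chromosome covariate, protein-coding genes only, and each library left out. Added after seeing the data were a covariate for choroid plexus (the mean log2 value of its list), the removal of LS replicates 2 and 3, and thinning to equal depth. The choroid plexus score differs between groups, so a fit with it also removes group differences that follow it. The explanation by a common factor was tested in several forms, all after the result was seen. The share of positive interactions was dropped, since it cannot tell whether a factor is common. List medians on the log2 and FPKM scales with libraries left out were replaced by a jackknife over animals within groups, whose interval was then widened by Bonferroni for all 105 pairs of the 15 lists with at least 5 raised genes, and the departures of all raised genes from the best common factor were added.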

Results

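RNA was measured in whole hippocampi of C57BL/6J mice, an inbred laboratory strain, at postnatal day 15. Each pup had received lipopolysaccharide (LPS, a bacterial cell wall component that triggers innate immunity) or saline under the skin on day 3, and LPS or saline into the abdomen on day 14. LPS was given at 5 mg/kg, and tissue was taken 24 h after the second injection. The 4 groups are named by the order of injections, with S for saline and L for LPS (SS, SL, LS and LL), and each held 3 animals. The libraries held between 16979666 and 24105022 fragments in the listed genes. SS libraries held 16979666 to 18425733, a range that includes the lowest SL library at 18258513. The highest depths were in LL, at 21926635 to 24105022. Of 54532 listed genes, 17687 were tested. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. The first principal component of these values held 37.8% of the variance and separated the SL libraries from the other 9.

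Marker genes of the choroid plexus, the secretory tissue that adjoins the hippocampus in the ventricle, differed in level between the libraries. Transthyretin (Ttr, chromosome 18, 20665250 to 20674324, mm10), its most abundant marker, was at 2280 ± 181 FPKM in SS, 765 ± 139 in SL, 383 ± 610 in LS and 2510 ± 504 in LL (SD, n = 3). Within LS, replicate 1 was at 1090 FPKM, replicate 2 at 47.7 and replicate 3 at 14.9. Libraries with Xist, the transcript of the inactive X chromosome, above 10 FPKM numbered 2 in SS and 1 in each other group, so both sexes were present in every group.

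**Figure D1:**
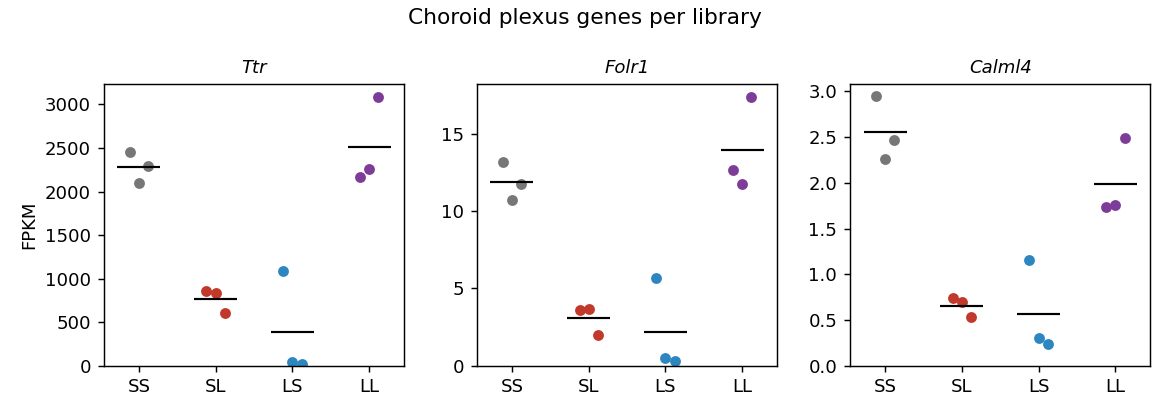
FPKM of 3 choroid plexus genes (Ttr, Folr1 and Calml4) in each library, by group, on linear axes. Points are libraries and bars are group means; LS replicates 2 and 3 hold Ttr at 47.7 and 14.9 FPKM, against 2090 to 2460 in SS.

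The comparison of SL with SS gives the response to a first encounter with LPS on day 14. SL hippocampi had far higher levels of acute-phase, chemokine and cytokine transcripts. Lipocalin 2 (Lcn2, an iron-sequestering acute-phase protein; chromosome 2, 32384633 to 32388252) was at 193 ± 80.5 FPKM in SL and 0.184 ± 0.19 in SS (n = 3 each), a log2 fold change of 8.10 (SE 0.47). Saa3, a serum amyloid A, rose by 8.07 (SE 0.38), and C3, the central complement component, by 6.41 (SE 0.28). Cxcl10, an interferon-induced chemokine, rose from 0.0345 ± 0.0299 to 31.6 ± 4.99 FPKM, and Tnf from 0.011 ± 0.0191 to 8.85 ± 0.902 FPKM. Il6 was listed at 0 in all SS libraries and at 0.939 ± 0.213 FPKM in SL. All 25 tested members of the list of NF-kB targets and inflammatory mediators rose, among them Il1b (4.54, SE 0.18), as did 23 of 24 acute-phase genes and 13 of 15 chemokines. Of these chemokines 1 fell. Lcn2 is a member of 4 of the lists. All 44 type I interferon-stimulated genes rose, including Isg15 (3.39) and Ifit1 (3.24), as did all 15 interferon-inducible GTPase genes, such as Gbp2 (3.81), and 18 of 19 genes of class I antigen presentation, such as H2-K1 (2.54). The counts adjusted over the list alone were 25, 24, 13, 44, 15 and 19 in the same order. Camera called each of these 6 lists higher, and with an estimated correlation the adjusted p lay between 0.00242 and 0.00876.

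Glial and vascular genes changed with them. Gfap, the astrocyte intermediate filament, rose from 87.2 ± 1.99 to 427 ± 100 FPKM, and 28 of 33 reactive astrocyte genes rose. Of 18 endothelial activation genes 15 rose, among them the leukocyte adhesion molecule Sele (4.33). All 9 neutrophil markers rose, led by S100a9 (6.55) and S100a8 (5.86), and 4 of 6 monocyte markers rose. Of 15 genes of resting microglia 9 fell and 2 rose. P2ry12, the microglial ADP receptor (chromosome 3, 59216272 to 59262871), was at 1.51 ± 0.371 FPKM against 14 ± 0.56 in SS, and Gpr34 and Siglech fell by 2.03 and 1.89 on the log2 scale. The camera call of that list had an adjusted p = 0.0638 with an estimated correlation. Of 21 cholesterol synthesis genes 18 fell, among them Hmgcs1 (-0.77) and Insig1 (-0.63), with an adjusted p = 0.00458 with an estimated correlation. Of 27 glutamatergic synapse genes limma called 0, as did limma voom, and 2 had an unadjusted p under 0.05. Of 7 red blood cell transcripts 6 fell, including Hbb-bt (-2.09), with an adjusted p = 0.0684 with an estimated correlation. Of 15 choroid plexus genes 5 fell, and 12 fell when adjusted over the list alone, with an adjusted p = 0.255 with an estimated correlation. Markers of other adjoining tissues fell as well, for 7 of 12 meningeal fibroblast genes, of which 1 rose, and 4 of 7 ependymal genes, with adjusted p of 0.28 and 0.233 with an estimated correlation. In all, 1249 genes were higher and 666 lower. Quantile normalization gave 1138 higher and 992 lower, and with the choroid plexus score as a covariate, chosen after seeing the data, 875 were higher and 353 lower.

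**Figure D2:**
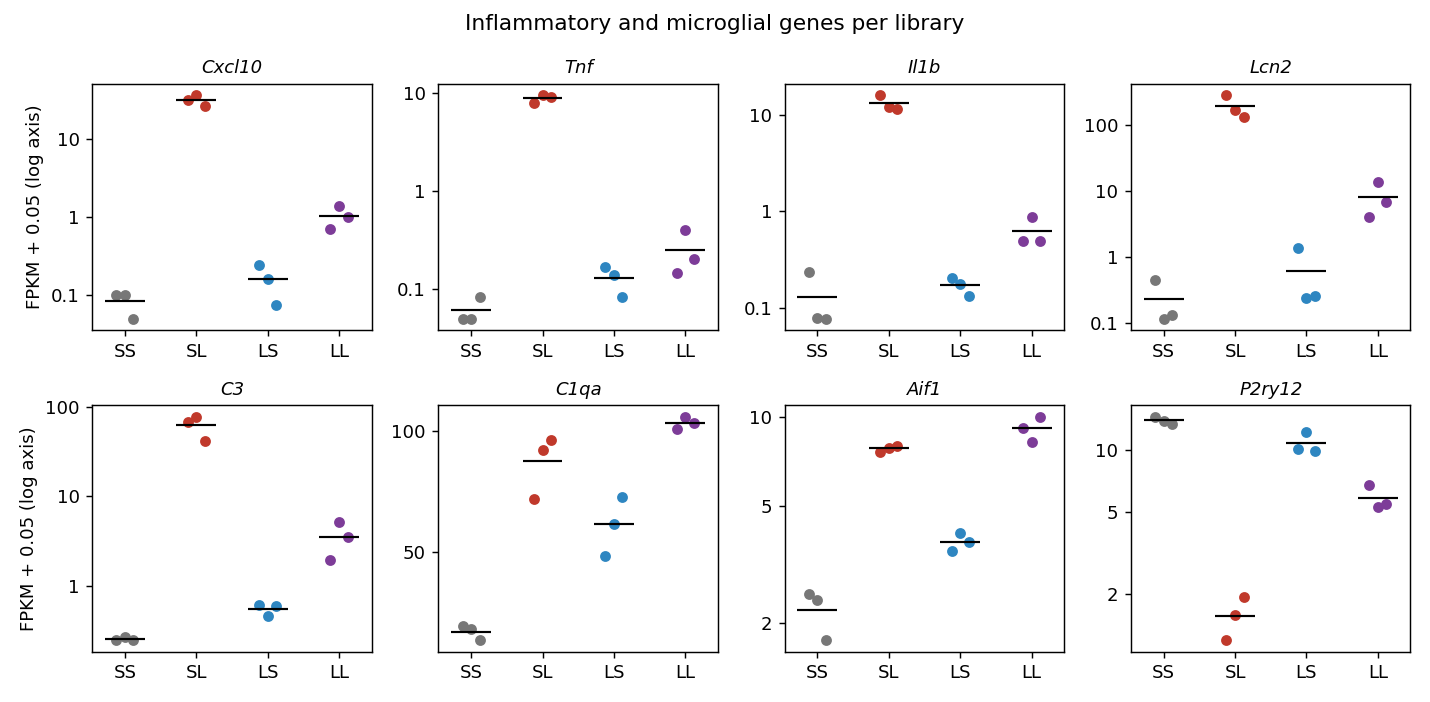
FPKM of 8 inflammatory and microglial genes in each library, by group, on logarithmic axes after adding 0.05. Points are libraries and bars are group means; Cxcl10 averages 31.6 FPKM in SL and 0.973 in LL, while Aif1 averages 7.76 in SL and 9.1 in LL.

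The comparison of LS with SS asks what remained on day 15 of LPS given on day 3 alone. Few genes passed the test. Adgre1, which encodes the macrophage antigen F4/80 (chromosome 17, 57358691 to 57483527), was at 4.43 ± 0.53 FPKM in LS and 1.89 ± 0.343 in SS, a log2 fold change of 1.05 (SE 0.11; limma adjusted p = 0.00767). Lyz2, a lysozyme of myeloid cells, rose by 0.93 (SE 0.11), the myeloid transcription factor Spi1 by 0.82 (SE 0.12) and the complement genes C1qa and C1qc by 0.86 (SE 0.13) and 0.62. Of 19 complement genes these 2 rose and 1, Cd59a, fell (-0.71, SE 0.12), and camera did not call the list, with an adjusted p = 0.0756 and an adjusted p = 0.797 with an estimated correlation. Of 25 innate receptors 1 rose, with 4 adjusted over the list alone. Camera at the preset correlation called this list higher (adjusted p = 0.000432). It also called NF-kB targets (0.00317), cell-cycle (2.18e-05), immature neuron (2.59e-05) and class I antigen presentation genes (0.0264) higher. Myelin (2.04e-13), choroid plexus (9.72e-21), heat shock (0.000432) and respiratory chain genes (0.00887) were called lower. Neither camera with an estimated correlation (0.466 for innate receptors) nor the directional fry test (0.171) called any of these lists. The mixed fry test asks for changes in either direction. It called innate receptors (adjusted p = 0.000135), cell-cycle (0.00652), choroid plexus (0.0106), myelin (0.0312), immature neuron (0.0455) and complement genes (7.26e-05). It did not call NF-kB targets, class I antigen presentation, heat shock or respiratory chain genes. Limma called 0 of 15 resting microglia, 0 of 16 damage-associated microglia and 0 of 8 border macrophage genes, where limma voom called 1, 0 and 1, and 6, 4 and 3 had an unadjusted p under 0.05. The mixed fry test called each of these lists (adjusted p = 0.00652, 0.00368 and 0.000416), and the directional fry test called none. Of the inflammatory genes named above, Il1b (0.11, SE 0.18), Tnf (0.18, SE 0.15), Cxcl10 (0.18, SE 0.17) and Lcn2 (0.52, SE 0.47) did not pass the test. Genes of the choroid plexus led the lower calls: Defb11 was at 1.24 ± 2.15 FPKM against 16.6 ± 0.252, and Calml4 fell by 1.62. These calls stand beside the low Ttr level of LS replicates 2 and 3. Of 15 choroid plexus genes 1 fell, and 15 fell when adjusted over the list alone, with an adjusted p = 0.466 with an estimated correlation. Of 19 myelin genes limma called 0 over all genes and limma voom called 5, 14 had an unadjusted p under 0.05, and 10 were lower adjusted over the list alone, with a median log2 fold change of -0.49 and an adjusted p = 0.466 with an estimated correlation.

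In all, 26 genes were higher and 29 lower, and 2230 genes had an unadjusted p under 0.05. The count of 55 rested on single libraries. It was 11, 6 and 2 without SS replicates 1, 2 and 3, it was 203, 10 and 6 without LS replicates 1, 2 and 3, and it was 32 without SL replicate 2 and 36 without LL replicate 1. It was 0 with only the 2 groups in the limma fit, where 1983 genes had an unadjusted p under 0.05, 1 with the choroid plexus score as a covariate and 2 without LS replicates 2 and 3, both chosen after seeing the data. It was 203 with library weights, 167 with limma voom, 170 with protein-coding genes only and 83 with a filter of 2 FPKM. Adgre1 was called with each of the 12 libraries left out in turn. The call of Lyz2 ended without SS replicate 2 or 3, those of Spi1, C1qa and C1qc without any SS replicate or LS replicate 2 or 3, and those of Defb11, Calml4 and Cd59a in 7, 9 and 9 of the 12 cases.

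The comparison of LL with LS gives the response to the same second injection in animals that had met LPS on day 3. Interferon-stimulated, antigen presentation, complement and chemokine genes rose. Of 44 type I interferon-stimulated genes 33 rose (43 adjusted over the list alone), of 19 class I antigen presentation genes 13 rose (18 over the list alone), and of 19 complement genes 12 rose (15 over the list alone). With an estimated correlation their adjusted p were 0.02, 0.016 and 0.00393. Of 15 chemokines 7 rose (9 over the list alone), with an adjusted p = 0.00892 with an estimated correlation. Of 24 acute-phase genes 6 rose, among them Saa3 (3.87, SE 0.38) and Lcn2 (3.02, SE 0.47), with 10 adjusted over the list alone and an adjusted p = 0.117 with an estimated correlation. Of 25 NF-kB targets 4 rose, with 9 adjusted over the list alone and an adjusted p = 0.152 with an estimated correlation. Ccl12, a monocyte-attracting chemokine, was at 14.4 ± 6.22 FPKM in LL and 0.798 ± 0.233 in LS, and Cxcl13, a B cell chemokine, was at 3.82 ± 0.687 against 0.101 ± 0.137. Aif1, the microglial protein IBA1, rose by 1.18 (SE 0.11). Tnf was at 0.203 ± 0.136 FPKM in LL and 0.0814 ± 0.0442 in LS and did not pass the test (0.26, SE 0.15). P2ry12 fell by 0.84 (SE 0.13). Of 9 neutrophil and 6 monocyte markers 2 each rose, and 4 of 7 red blood cell transcripts fell, with adjusted p of 0.245, 0.0586 and 0.0899 with an estimated correlation. Of 15 choroid plexus genes 13 rose beside the difference in Ttr between these groups, with an adjusted p = 0.0899 with an estimated correlation. In all, 424 genes were higher and 46 lower. The count of 470 became 231 and 234 without LS replicates 2 and 3, and 227 and 222 without LL replicates 2 and 3. It became 251 with only the 2 groups in the fit, 760 with library weights, 33 with the choroid plexus score as a covariate and 69 without LS replicates 2 and 3 together.

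The interaction asks whether the response to the second injection differed between animals given LPS and saline on day 3. Cytokine, chemokine, acute-phase and neutrophil genes responded less after LPS on day 3. The interaction was negative for 23 of 25 NF-kB targets, 21 of 24 acute-phase genes, 11 of 15 chemokines, 24 of 33 reactive astrocyte genes and all 9 neutrophil markers, and the counts adjusted over the list alone were 24, 23, 12, 26 and 9. With an estimated correlation these lists had adjusted p between 0.00535 and 0.0311. Cxcl10 (chromosome 5, 92346638 to 92348889) had an interaction of -4.64 (SE 0.24), with 31.6 ± 4.99 FPKM in SL and 0.973 ± 0.33 in LL. Tnf (chromosome 17, 35199381 to 35202007) had -3.93 (SE 0.21), Il1b (chromosome 2, 129364570 to 129371139) -3.78 (SE 0.25), and Ccl3 -5.64 (SE 0.43). Ptx3, a pentraxin, had -5.19 (SE 0.43) and was at 65.2 ± 38.5 FPKM in SL and 1.44 ± 0.0952 in LL. Acod1, the itaconate-producing enzyme of activated macrophages, had -4.78 (SE 0.23). Gfap had -2.07 (SE 0.18). Of 44 type I interferon-stimulated genes 20 were negative (36 adjusted over the list alone), with an adjusted p = 0.083 with an estimated correlation. Aif1, with -0.46 (SE 0.15), did not pass the test.

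Some genes of resting microglia and of cholesterol synthesis, lists with many falls in SL, had positive interactions. The interaction was positive for 8 of 15 resting microglia genes, including P2ry12 (2.03, SE 0.19), and for 10 of 21 cholesterol synthesis genes, including Hmgcs1 (0.54), and the counts adjusted over the list alone were 12 and 15. It was also positive for all 15 choroid plexus genes, such as Folr1 (4.91, SE 0.85), as Ttr was lower in SL and LS than in SS and LL, with an adjusted p = 0.0716 with an estimated correlation. It was positive for 4 of 7 ependymal and 3 of 12 meningeal fibroblast genes, with adjusted p of 0.0954 and 0.344 with an estimated correlation. In all, 378 genes were called with a positive and 564 with a negative interaction. With the choroid plexus score as a covariate 24 were positive and 76 negative, and without LS replicates 2 and 3 together 134 were positive and 286 negative. Among the 1127 genes raised by the second injection averaged over the first, 987 had a negative estimate, with a median of -0.49. The raised genes were chosen anew in other settings. The median was -0.60 over 1032 genes with the choroid plexus score as a covariate and -0.61 over 844 genes without LS replicates 2 and 3. Among the 443 genes lowered by the second injection averaged over the first, 378 had a positive estimate, with a median of 0.19.

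**Figure D3:**
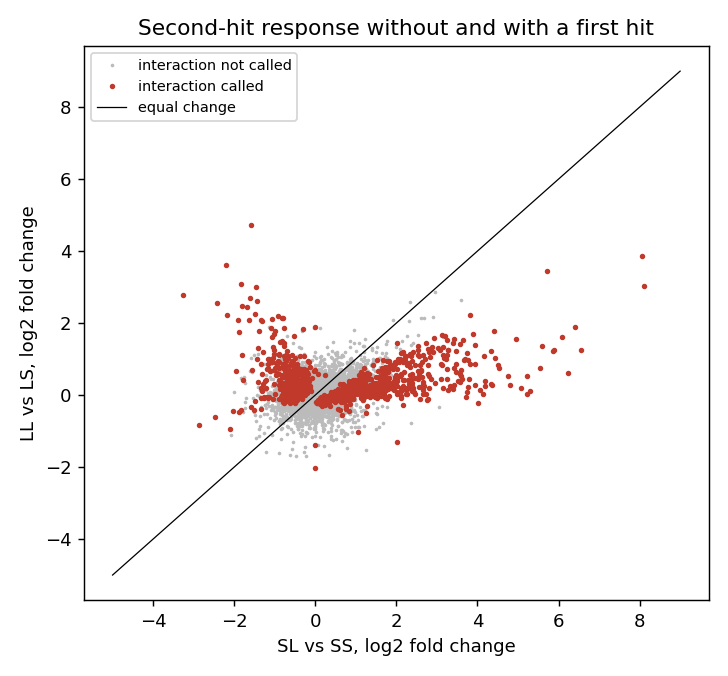
Log2 fold change of each tested gene in SL against SS (horizontal) and in LL against LS (vertical), with genes whose interaction was called in red and the line of equal change. Most of the genes with the largest rises in SL lie below the line, as Ccl3 does with an interaction of -5.64. Picking genes by their rise in SL favours that position, so it is not a test of the interaction.

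Across the 17687 genes, which are not independent replicates, the fold changes of SL against SS and of LL against LS had a Pearson correlation of 0.285 and a Spearman correlation of 0.122. These comparisons share no library. Of the 1249 genes higher in SL and the 424 higher in LL, 278 were shared, against 29.9 for independent lists, and 1 of the 1249 was called lower in LL than LS. Of the 666 lower genes and the 46 lower genes, 19 were shared, against 1.73, and 45 of the 666 were called higher in LL than LS. No reference was computed for calls in opposite directions. Both comparisons take the spread of each gene from all 12 libraries, so independent lists are a low reference. With the choroid plexus score as a covariate the Pearson correlation was -0.071. That fit has a single slope per gene for the score, which was lower in SL than SS and higher in LL than LS. Error in the slope therefore moves the fold changes of these comparisons in opposite directions. The change of sign is thus partly built in and says nothing certain about the responses. For LS against SS and LL against SL the Pearson correlation without the score was -0.087, with a Spearman correlation of 0.03.

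**Figure D4:**
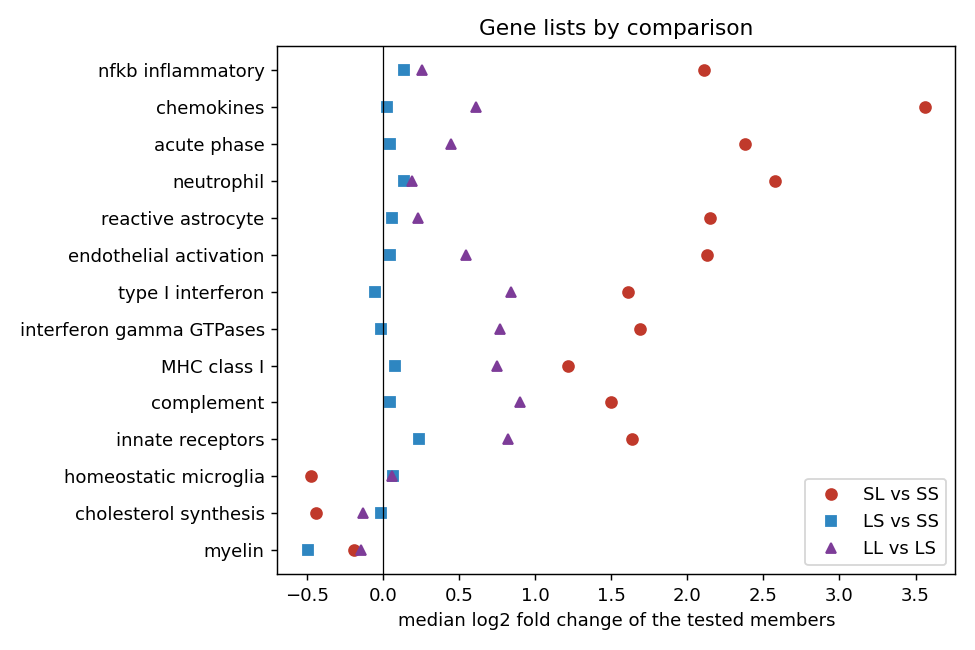
Median log2 fold change of the tested members of 14 gene lists in SL against SS, LS against SS and LL against LS. The NF-kB list has medians of 2.11, 0.14 and 0.26 in that order, and the type I interferon list 1.61, -0.05 and 0.84.

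LL was compared directly with SL, both taken 24 h after LPS on day 14. Inflammatory genes were lower and resting microglia genes higher in LL. Of 25 NF-kB targets 24 were lower, as were 22 of 24 acute-phase genes, 12 of 15 chemokines and 37 of 44 type I interferon-stimulated genes. All 9 neutrophil markers and 4 of 6 monocyte markers were lower as well, with adjusted p of 0.0111 and 0.022 with an estimated correlation. Mmp3, a matrix metalloproteinase, was at 22.1 ± 12.6 FPKM in SL and 0.0546 ± 0.0108 in LL. Of 15 resting microglia genes 14 were higher, including P2ry12 (1.66, SE 0.13), Trem2 (1.51) and Tmem119 (0.99, SE 0.13). Of 21 cholesterol synthesis genes 14 were higher. Fabp7, a lipid-binding protein of radial glia and astrocytes, was at 68.4 ± 14.8 FPKM in LL and 20.3 ± 4.16 in SL, and Mrc1, the mannose receptor of perivascular macrophages, was higher by 1.70 (SE 0.18). With an estimated correlation the adjusted p of these 6 lists lay between 0.00379 and 0.0413. Of 15 choroid plexus genes 5 were higher, with an adjusted p = 0.2 with an estimated correlation. Of 12 meningeal fibroblast genes 5 were higher and 2 lower, and 3 of 7 ependymal and 3 of 8 border macrophage genes were higher, with adjusted p of 0.308, 0.105 and 0.144 with an estimated correlation. In all, 588 genes were higher and 966 lower. Quantile normalization gave 851 higher and 873 lower. The count of 1554 became 913 without SL replicate 2, 1007 without LL replicate 1, and 778 with the choroid plexus score as a covariate.

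LL against SS compares both injections of LPS with none. Innate receptor, interferon-stimulated and complement genes were higher. Aif1 was at 9.1 ± 0.892 FPKM in LL and 2.16 ± 0.409 in SS, and C1qa (chromosome 4, 136895917 to 136898803) was at 105 ± 3.61 against 31.7 ± 1.36. Lyz2 rose by 2.72 (SE 0.11), Cd52 by 2.66 (SE 0.21) and Cd72 by 2.46 (SE 0.14). Of 44 type I interferon-stimulated genes 31 rose, as did 19 of 25 innate receptors and 12 of 19 complement genes, with adjusted p of 0.0193, 0.00251 and 0.00251 with an estimated correlation. Of the markers of blood cells, 3 of 9 neutrophil genes rose, among them S100a8 (1.52, SE 0.23), as did 1 of 6 monocyte genes, and 3 of 7 red blood cell transcripts fell, with adjusted p of 0.151, 0.047 and 0.0872 with an estimated correlation. Of 15 resting microglia genes 4 rose and 2 fell (7 and 6 adjusted over the list alone), and camera did not call the list, with an adjusted p = 0.148 and an adjusted p = 0.598 with an estimated correlation. Cx3cr1, the fractalkine receptor, rose by 0.80, and P2ry12 fell by 1.21 on the log2 scale. Of 22 cell-cycle genes 6 rose (15 adjusted over the list alone), among them Mcm3 (1.14) and Mcm5 (0.68), with an adjusted p = 0.013 with an estimated correlation. Of 19 myelin genes 8 fell (17 adjusted over the list alone), with an adjusted p = 0.114 with an estimated correlation. Mal, a myelin proteolipid (chromosome 2, 127633226 to 127656695), was at 22 ± 4.88 FPKM in LL and 46.6 ± 4.04 in SS, and Mog, a myelin surface glycoprotein, at 18.5 ± 3.88 against 35.8 ± 2.63. The call of Mal ended without SS replicate 1 or 3 or LL replicate 2, with log2 fold changes of -1.19 to -0.89 over the 12 libraries left out, and that of Mog without SS replicate 2. Mbp, with -0.63 (SE 0.17), did not pass the test. In LL against LS limma called 0 of 19 myelin genes lower and 1 higher. The higher gene was Enpp2, at 176 FPKM in LL and 42.5 in LS, which like Ttr was lower in SL and LS than in SS and LL. In LS and SL, Mal was at 22.2 ± 3.95 and 43.8 ± 11.8 FPKM, and Mog at 23 ± 3.77 and 28.6 ± 5.21. Averaged over the second injection, the lower level of Mal with LPS on day 3 was called with each of the 12 libraries left out. Ttr averaged 2510 FPKM in LL and 2280 in SS, and limma and limma voom called 0 of 15 choroid plexus genes, with 0 at an unadjusted p under 0.05 and an adjusted p = 0.991 with an estimated correlation. In all, 376 genes were higher and 50 lower, and the count of 426 became 278 without LL replicate 2.

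Averaged over the first injection, LPS on day 14 raised 1127 genes and lowered 443, and quantile normalization gave 993 and 637. Averaged over the second injection, LPS on day 3 raised 375 genes and lowered 640, and quantile normalization gave 538 and 597. Without SL replicate 2 the latter count of 1015 became 639. Since the interaction was called for 942 genes, these averages combine unlike responses. Without LS replicates 2 and 3 the counts of 1570 and 1015 became 1040 and 430.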

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

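The tests of a common weakening factor, of choroid plexus for single gene sets and of microglial number were chosen after the result was seen, as were the choroid plexus covariate and the thinning to equal depth. The response to LPS on day 14 differed between animals given LPS and saline on day 3, by the test of the difference itself, for 564 genes with a lower and 378 with a higher estimate. The interaction was -4.64 for Cxcl10 (limma adjusted p = 5.45e-06), -3.93 for Tnf, -3.78 for Il1b, -5.08 for Lcn2, -4.51 for C3 and 2.03 for P2ry12. Lcn2 lost its call with limma voom. Of 100 splits in which first-injection labels were redrawn within each second-injection group, 1, the real split, gave as many as 942 calls, and the highest other gave 772. These splits test whether the first injection had any effect, not the interaction: with the labels of SS and LS exchanged and the others kept, a split not among the 100, the contrast becomes the first-injection average and gave 1015 calls. They therefore do not tell whether chance accounts for the count of 942.

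The smaller rise of second-injection genes after LPS on day 3 had a median interaction of -0.51 with all libraries thinned to the smallest. With the choroid plexus score in the model it was -0.6. The raised genes were chosen anew in each setting (1092 and 1032 genes), so these medians are not over the same 1127 genes. Both stayed negative, which argues against library depth and against choroid plexus as the whole cause. For a weaker second exposure that scales responses alike, NF-kB and type I interferon genes, lists picked after their medians were seen, kept a median share of 0.0617 and 0.34 of their FPKM response, a difference of 0.278 (jackknife 95% interval 0.143 to 0.412, or -0.0527 to 0.608 widened for the choice among 105 pairs of lists), and of 0.225 without LS replicates 2 and 3. Of all 1127 raised genes 20.1% departed from the log2 factor with the fewest departures, against 9.14% to 21.4% with each library left out, 2.04% without LS replicates 2 and 3 and 0.0887% with the choroid plexus score. The 226 departing genes had a median departure of 0.55 (median SE 0.13) with all libraries and no score. It was 0.52 (0.18) without LS replicates 2 and 3 and 0.49 (0.25) with the score. The error grew, but these genes were chosen and signed by their departure in the first of these fits. Their kept size is therefore partly built in, and a common factor is neither shown nor excluded. LPS on day 3 and a weaker exposure that acts unequally on different genes also stay open, as untested.

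Genes lower in LS than SS followed the choroid plexus score within groups, with a median residual correlation of 0.55 over 28 genes outside the list. This was above 100% of random lists, which were drawn without regard to co-expression. Only 1 list gene was called lower, so Defb11 and Calml4 are not both in the list. The 28 genes thus still hold choroid plexus genes, for which the correlation is partly built in. Choroid plexus, by its amount or its expression, stays a candidate explanation for them. For the 363 genes with a higher interaction outside the list the median was 0.47, under the 0.5 set as the bound, and choroid plexus and the first injection cannot be told apart for them. For the 26 genes higher in LS the median was -0.14, at percentile 8.53 of random lists. Within groups the score varied mainly in LS, at 2.34, 0.28 and 0.03 in replicates 1, 2 and 3. All of these correlations thus rest largely on 1 library. They do not decide whether choroid plexus accounts for the 28 lower genes or for the 26 higher genes. With the score in the model 1 of the 26 higher genes was called and all 26 estimates stayed above 0. The median log2 fold change went from 0.68 to 0.60 and the median SE from 0.09 to 0.15, so the calls ended mainly by the larger error.

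Aif1 and C1qa were higher in LL than SS, and of the homeostatic microglia genes 2, P2ry12 and Slc2a5, were called lower and 4 higher. The list as a whole had an adjusted p = 0.148, and an adjusted p = 0.598 with an estimated correlation. More microglia alone would raise all of them, so the 2 lower genes argue against it as the whole explanation. The call of Slc2a5 ended in 10 of the 12 cases with a library left out, and that of P2ry12 in 0. A change of microglial number together with a change of expression may still be consistent with the 2 lower genes, and was not tested.

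For the 5 comparisons of 2 groups, 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many calls. The real count and the highest other were 1915 and 0 for SL against SS, 55 and 0 for LS against SS, 470 and 2 for LL against LS, 1554 and 1 for LL against SL, and 426 and 1 for LL against SS. For the first injection averaged over the second, 1 of 100 splits gave as many as 1015 and the highest other gave 630. For the second averaged over the first, 1 of 100 gave as many as 1570 and the highest other gave 1052. With labels exchanged in a single pair of groups, splits not among those drawn, both averages become the interaction, with 942 calls. A share of 1 in 100 argues against chance assignment of the labels redrawn, without excluding it. These splits test whether the injection redrawn had any effect, so they do not single out its average.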

How the results depend on the processing

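The choroid plexus covariate, the removal of LS replicates 2 and 3 and the thinning were chosen after seeing the data; the cause of the changes below was not tested unless stated. With the covariate the counts were 1228 for SL against SS, 1 for LS against SS, 33 for LL against LS, 778 for LL against SL and 100 for the interaction. The correlation of SL against SS with LL against LS was -0.071, and that of LS against SS with LL against SL was -0.367. In each pair the score differs in opposite directions, so error in its shared slope lowers these correlations by construction. Estimates that changed sign were Aqp1 (-0.17), Clic6 (-0.17) and Enpp2 (-0.05) in LL against LS and Ttr (-2.37), Aqp1 (-0.71) and Clic6 (-0.36) in the interaction, and these genes belong to or follow the score. Lists that changed direction had adjusted p of 0.916 (glutamatergic synapse), 0.0191 (respiratory chain), 0.669 (ependyma) and 0.0149 (meninges) in LL against LS, and 0.000923 (myelin) and 0.963 (meninges) in the interaction. Without LS replicates 2 and 3 the counts were 2 for LS against SS, 69 for LL against LS, 420 for the interaction, 1040 for the second injection averaged and 430 for the first, the latter correlation was -0.014, and the choroid plexus list changed direction in both averages (1.92e-05 and 1.43e-07).

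For LS against SS the count was 83 with a filter of 2 FPKM, 0 with the 2 groups alone, 203 with library weights, 167 with limma voom and 170 with protein-coding genes. For LL against LS it was 251 with the 2 groups alone and 760 with library weights. The first correlation was 0.363 with a filter of 2 FPKM and 0.352 with limma voom. With an estimated correlation 91 of 191 list calls held over all comparisons. Fewer samples, fewer genes tested or a set-wise correlation is part of the construction of these settings. With single libraries left out the counts ranged from 1462 to 2001 for SL against SS, 2 to 203 for LS against SS, 222 to 560 for LL against LS, 913 to 1611 for LL against SL, 278 to 487 for LL against SS, 649 to 1016 for the interaction, 1266 to 1587 for the second injection and 639 to 918 for the first. The medians of the interaction, over raised and lowered genes chosen anew each time, ranged from -0.57 to -0.46 and from 0.12 to 0.24. The correlations ranged from 0.238 to 0.298 and from -0.11 to -0.061, and the list calls from 182 to 200.

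Replicate numbers are not stated to pair animals, and 0 of 18 same-numbered pairs correlated above 0.1. The replicate block gave 1911, 41, 426, 1542, 406, 915, 1531 and 961 calls in the order of the 8 comparisons above, medians of -0.50 and 0.20, correlations of 0.285 and -0.087 and 195 list calls, and 34 of 620 results for named genes changed their side of the threshold. Of 12 libraries, 6 correlated best with a library of their own number. The mean correlation was 0.021 for same-numbered pairs and -0.011 for other pairs. These values do not settle whether animals were paired. Depth limits low levels: 1 fragment in 1 kb is worth 0.0402 to 0.0587 FPKM.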

Other observations

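Some gene groups not described above also changed. Of 20 immediate early genes 6 were called higher 24 h after LPS in SL, among them Fos (1.40) and Junb (1.2), and 1 was called lower. The list had an adjusted p = 0.328 with an estimated correlation. For this list limma and limma voom called 0 of 20 in LL against SS, where 1 had an unadjusted p under 0.05. The interaction was negative for 5 and positive for 1 of the 20. The list had an adjusted p = 0.377 in the interaction with an estimated correlation. Heat shock and unfolded-protein genes rose in SL for 7 of 20, led by Hspb1 (1.79), with an adjusted p = 0.161 with an estimated correlation. Glucocorticoid targets rose in SL for 12 of 19, including the metal-binding Mt2 (2.44), and 13 of 19 were lower in LL than SL, with adjusted p of 0.00784 and 0.0111 with an estimated correlation.

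Some red blood cell transcripts were lower in both groups given LPS on day 14. Hba-a1 averaged 146 FPKM in SS, 155 in LS, 53.7 in SL and 69 in LL, and 6 of 7 such genes fell in SL against SS and 4 of 7 in LL against LS, with adjusted p of 0.0684 and 0.0899 with an estimated correlation. Markers of neighbouring brain regions gave few calls. In SL against SS limma and limma voom called 0 of 10 thalamus genes, with 0 at an unadjusted p under 0.05, and limma called 1 of 11 neocortex genes, with adjusted p of 0.616 and 0.982 with an estimated correlation.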
